A study of Mus musculus with 8 samples.

How the data were processed

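RNA of the nuclear fraction was measured in mouse embryonic stem cells of the C57BL/6 strain, kept in serum with LIF (a cytokine that holds these cells in the undifferentiated state) and inhibitors of GSK3 and MEK. Per the labels' protocols, RNA was purified with Trizol, depleted of ribosomal RNA with RiboMinus and made into libraries with the SMARTer Stranded Total RNA-Seq kit v2. No feeder layer is named. The groups, Mettl14 control, Mettl14 cKO, Mettl3 control and Mettl3 cKO, and the replicate numbers come from the sample titles; each group has 2 samples. The exons deleted and the time after deletion are not given in the sources used here.

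The deposited values are raw counts of reads per gene, 1 table per sample with 54446 genes. Per the submitters' processing notes, CASAVA, Trimmomatic 0.38, HISAT2 2.1.0 and HTSeq were used with the mm10 genome. The annotation release, the strand setting of HTSeq and the treatment of reads that map to several places are not given in the sources used here. So overlapping genes on opposite strands and near-identical copies can share or lose reads: 27 of the 111 genes named in the text overlap another gene of at least 1 CPM, 17 of them on the opposite strand. Gene IDs were matched without their version to GENCODE M21, which gave symbols, classes and coordinates for 54409 genes and none for 37; 0 lines named no gene.

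Total counts ran from 17235889 to 20086128 per library. Samples of a group were compared before averaging: their log2 CPM correlated at r of at least 0.995, and their counts differed by more than sampling noise in every group (chi-square per degree of freedom 1.43 to 2.08), so none was treated as a copy. Genes were kept with edgeR's filterByExpr at a minimum count of 10, which left 21782. edgeR 4.0.16 in R 4.3.3 was used with TMM scaling, robust glmQLFit and glmQLFTest, in 1 fit of all 8 libraries with 4 group means and 4 residual degrees of freedom; the common dispersion was 0.000571. The contrasts were each cKO minus its own control, the Mettl14 change minus the Mettl3 change, and Mettl14 control minus Mettl3 control. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. CPM values use TMM-scaled library sizes, and log2 fold changes are given with their standard errors.

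The 31 gene lists were fixed in advance from general knowledge of these cells. They cover the m6A writer complex, m6A readers and erasers, core, naive and formative pluripotency, primitive endoderm, trophectoderm, mesoderm, neuroectoderm, Hox clusters, Polycomb, H3K27 and H3K4 enzymes, H3K9 and DNA methylation repressors, the 2-cell-like state, germline genes, p53 targets, interferon response, ATF4 and unfolded protein response, immediate-early genes, ERK and Wnt targets, cholesterol synthesis, glycolysis, imprinted genes, nuclear long noncoding RNAs, fibroblast markers, proliferation, mitochondrial mRNAs, ribosomal proteins, histones and small nucleolar RNAs. Each was tested with camera at a preset inter-gene correlation of 0.01, adjusted over lists within a contrast, and again with an estimated correlation; fry (limma 3.58.1) was run beside it, which tests whether a list moves one way on balance and does not compare it with other genes. Members were counted past the threshold over all genes tested and adjusted over the list alone. Of the fibroblast markers tested, 0 are in another list and 12 have at least 10 CPM in Mettl14 control.

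Named genes were fixed by rule. For each knockout these were Mettl3 and Mettl14, then among called genes with an average log2 CPM of at least 1 and every cKO library on the same side of its own controls, the 7 highest and 7 lowest log2 fold changes without predicted or clone names and pseudogenes, and up to 2 members of each list with the smallest p. For the difference and the controls the 6 highest and 6 lowest were taken, and for genes changed in both knockouts the 6 highest and 6 lowest means. Not all genes so chosen are reported here. Genes outside the rule are said to have been chosen after their values were seen. No fold is given for genes with at most 3 counts in each library of a line.

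The test across genes was tested on simulated data with the real library sizes and 200 changed genes among 21782. Each gene was given its mean over all 8 libraries in every group. The real differences between groups were thus left out, and recovery of genes with few counts in only some groups is not described. For Mettl14, 46.1% of genes changed by 0.5 on the log2 scale and 51.0% of those changed by 1 were called, 91.8% and 100.0% among genes with an average log2 CPM of at least 3. For Mettl3 the shares were 46.9% and 63.7%, and 89.8% and 100.0% among the abundant genes. For the difference they were 33.7% and 54.3%, and 68.9% and 97.9%, and for the controls 44.8% and 64.4%, and 91.1% and 100.0%. A recovery of over 60% of all genes changed by 1 had been required at first; Mettl14 and the difference fell short of it, as many tested genes have few counts, and the requirement was then set to over 90% of abundant genes. Unchanged genes were called 6, 7, 5 and 8 times in these 4 comparisons.

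The alternatives were RLE and upper-quartile scaling, no low-count filter, at least 1 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, a separate fit per comparison, the replicate number as a block, a 2-fold limit, an adjusted p under 0.01, leaving out abundant and structural RNA genes, and leaving out each library in turn, which leaves an arm with 1 sample that is taken to vary like the other groups. With a library left out, the low-count filter was applied anew and kept 23509 to 24441 genes. Scaling and the tested members of a list could therefore change as well. Counts over genes with an average log2 CPM of at least 3 were added after seeing the data. Reads of silent genes were summed over 1460 olfactory and vomeronasal receptor genes, and genes that resemble the major satellite repeat were taken as those with at least 40% of their transcript's 15-mers in its consensus, which was written from general knowledge and not taken from a reference. For GC content, the median log2 fold change of genes of like GC percent, in 20 bins of 10095 genes, was subtracted. Reads of other assays of the study were not used here.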

Results

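Nuclear RNA was measured in mouse embryonic stem cells in which Mettl14 or Mettl3 had been knocked out conditionally (cKO), each beside control cells of its own line. METTL3 is the catalytic subunit and METTL14 its partner in the complex that writes N6-methyladenosine (m6A), a methyl mark on adenosines of RNA. The design text states that changes of nuclear RNA upon either knockout were examined, and the series title sets METTL14 apart from m6A, so the comparisons are each knockout against its own control, the difference between the knockouts, and the background difference between the controls. The 8 libraries formed 4 groups of 2: Mettl14 control, Mettl14 cKO, Mettl3 control and Mettl3 cKO. Their total counts were 18751234 and 18982929 for Mettl14 control, 18618885 and 20086128 for Mettl14 cKO, 17909801 and 17235889 for Mettl3 control and 17449453 and 17427113 for Mettl3 cKO. Nothing in the labels says that the 2 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Adjusted p-values of single genes are those of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and those of lists are from camera with the same adjustment over lists.

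The targeted genes were lower in the libraries labelled for their knockout. Mettl14 (ENSMUSG00000028114.16, chromosome 3, 123368297 to 123386108 on the minus strand in mm10) had 56.6 ± 2.34 CPM (counts scaled to library size, SD, n = 2) in Mettl14 control and 29.0 ± 1.72 in Mettl14 cKO, 51.2% of control. On the log2 scale it fell by 0.96 ± 0.07 (SE, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 1.2e-26), and in Mettl3 cKO its log2 fold change was 0.04 (adjusted p = 0.78). Mettl3 (ENSMUSG00000022160.18, chromosome 14, 52294841 to 52305128, minus strand) had 37.0 ± 1.29 CPM (SD, n = 2) in Mettl3 control and 19.2 ± 0.894 in Mettl3 cKO, 51.9% of control. It fell by 0.95 ± 0.08 (SE, adjusted p = 1.2e-21). In Mettl14 cKO its log2 fold change was 0.02 (adjusted p = 0.836). Counts over a whole gene do not show which exons were deleted, and the part of Mettl3 that overlaps Tox4 on the opposite strand cannot be separated where counting ignored strand. Mettl14 was also low in the Mettl3 line, at 28.4 ± 2.38 CPM (SD, n = 2) in Mettl3 control, and was higher in Mettl14 control by 0.99 ± 0.07 on the log2 scale (SE, edgeR's test, adjusted p = 1.5e-28).

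**Figure D1:**
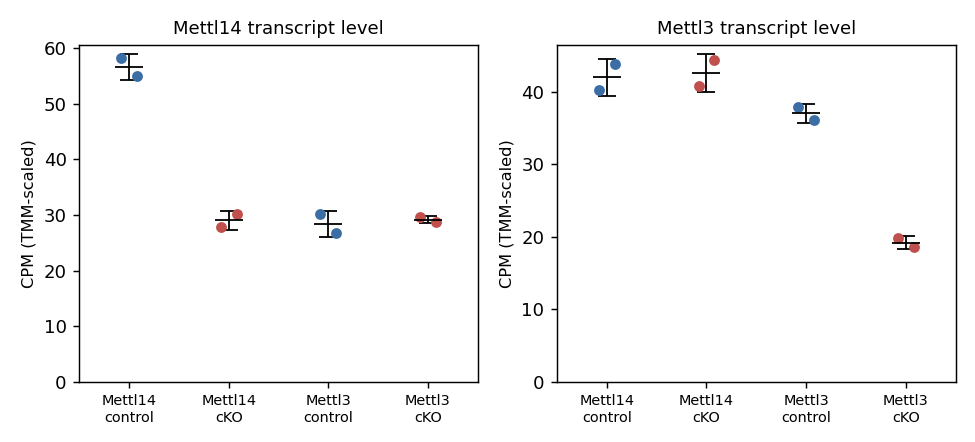
CPM of Mettl14 and Mettl3 in each library (points), with the group mean and SD (black bars, n = 2), for the 4 groups on the x axis. Mettl14 falls from 56.6 to 29.0 CPM in Mettl14 cKO, and Mettl3 from 37.0 to 19.2 CPM in Mettl3 cKO.

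In Mettl14 cKO, transcripts of the pluripotency network fell and those of cholesterol synthesis and of fibroblast markers rose. Sox2 fell by 1.95 ± 0.06 on the log2 scale, as did Klf4 (-1.45 ± 0.04) and Pou5f1, which encodes OCT4 (-1.22 ± 0.03) (SE, n = 2 against 2). Cyp51, a sterol demethylase, rose by 1.39 ± 0.03 and Col1a2, a fibrillar collagen chain, by 1.54 ± 0.03. In all, 8801 of 21782 tested genes changed, 3921 up and 4880 down, of which 1035 and 403 changed at least 2-fold. Genes with an average log2 CPM below 1 made up 646 of these rises and 191 of these falls. The 2-fold counts were not split by abundance, so their balance may rest on genes with few counts. This comparison asks which nuclear RNAs change when METTL14 is lost. A value in brackets after a gene is its log2 fold change.

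By the rule fixed in advance, the highest rises in Mettl14 cKO were those of Rtl1 (3.13 ± 0.18), an imprinted retrotransposon-derived gene (chromosome 12, 109589193 to 109600330), Ccdc107 (2.63), the small nuclear RNA gene Rnu1b6 (2.44), Gpnmb (2.13), a membrane glycoprotein gene, Mamdc2 (2.13), Snord23 (2.11) and the mitochondrial valine transfer RNA mt-Tv (2.11). Rtl1 stood at 1.61 CPM in control and 14.2 in cKO. Because microRNA genes lie opposite to it and Ccdc107 shares sequence with the RNA gene Rmrp, the source of both rises is uncertain. The call of mt-Tv was lost without Mettl14 control replicate 1 (adjusted p = 0.0739) and without either Mettl14 cKO library (0.0692 and 0.0644; range over all alternatives 3.4e-117 to 0.0739). The lowest were 5S ribosomal RNA genes of one near-identical family, from n-R5s136 (-6.04) and n-R5s194 (-6.02) through n-R5s115 (-5.68), n-R5s156 (-5.14) and n-R5s56 (-5.07) to n-R5s193 (-4.95), and Lars2, which fell by 4.36. In Mettl14 cKO these 5S genes had 1 to 90 counts per library. Their reads can be split among copies, and Lars2 shares sequence with the predicted genes Gm15564 and AA474408, so these values are uncertain. Genes that the annotation classes as ribosomal RNA together took 0.0368 and 0.0422% of counts in Mettl14 control and 0.0093 and 0.0095% in Mettl14 cKO. Ribosomal RNA-derived genes of another class, such as Mir6236, are not in these shares. Whether ribosomal RNA was depleted alike in these libraries was not tested. Among other protein-coding genes, chosen after their values were seen, Cited2 fell by 2.18 ± 0.08, as did Zfp296 (-2.17 ± 0.12) and Chchd10 (-1.99 ± 0.08).

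Of the pluripotency lists, 1 of 13 core members rose and 11 fell, with a median of -0.37. L1td1 fell by 0.85, while Tdgf1, which rose by 0.12, and Sall4, at -0.07, were named after their values were seen. Among naive pluripotency genes, 3 of 20 members rose and 14 fell (median -0.30), including Tet2 (-0.66) and Nanog (-0.43). Fibroblast markers moved the other way in the same libraries: 18 of 21 members rose and 0 fell (18 and 1 adjusted over the list alone), with a median of 1.09. Fbln2 rose by 1.56, but Col1a1 by 0.32, from 269.9 to 338 CPM. Both pluripotency lists and the fibroblast list were called by camera with an estimated correlation (adjusted p = 0.0075, 0.0274 and 0.0043). The genes of primitive endoderm, the extraembryonic lineage beside the epiblast, included 8 of 16 members that rose. Among them were the basement membrane genes Col4a1 (1.05) and Sparc (0.71). The list had an adjusted p = 0.0505 with an estimated correlation, which misses the threshold. Col4a1 and Sparc had up to 12341 and 29005 counts per library in Mettl3 control, against 2474 and 10974 in Mettl14 control. Fibroblast markers were likewise higher in Mettl3 control.

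Chromatin regulators and m6A readers were mostly lower. Falls also outnumbered rises among the 10099 tested genes with an average log2 CPM of at least 3, where 2593 rose and 4129 fell. Camera compared each list with all tested genes, so the list calls are not adjusted for abundance. 0 of 14 genes for m6A readers and erasers rose and 10 fell (median -0.45), including Prrc2a (-1.26) and the nuclear reader Ythdc1 (-0.79). Of the Polycomb components, 1 of 32 members rose and 17 fell (1 and 18 adjusted over the list alone) with a median of -0.36. Ezh2, the H3K27 methyltransferase, fell by 0.97, as did Epop (-0.997). For the H3K27 and H3K4 demethylases and methyltransferases, 0 of 18 members rose and 14 fell (0 and 15 adjusted over the list alone), including Kdm5b (-0.97), Kdm1a (-0.97) and the H3K27 demethylase gene Kdm6b, named after its value was seen, (-1.77). Among H3K9 and DNA methylation repressors, 0 of 24 members rose and 19 fell (1 and 19 adjusted over the list alone), including the HP1 gene Cbx3 (-1.04) and Mphosph8 (-0.92). With an estimated correlation, these 4 lists had adjusted p = 0.0091, 0.0274, 0.0075 and 0.0274 in that order. In the writer complex, 2 of 8 genes rose and 3 fell (2 and 4 adjusted over the list alone); besides Mettl14, Zc3h13 was lower (-1.04). The list's call was lost with an estimated correlation (adjusted p = 0.161) and without Mettl3 control replicate 1 (adjusted p = 0.0543), and its median of -0.03 turned positive with upper-quartile scaling (0.014) and without Mettl14 cKO replicate 1 (0.011), and was -0.088 without replicate 2 and -0.073 without Mettl14 control replicate 1.

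In cholesterol synthesis, 22 of 22 genes rose and 0 fell, with a median of 0.99 and an adjusted p = 0.00221 with an estimated correlation. Akap9 overlaps Cyp51 on the opposite strand. Transcripts of the mitochondrial genome went down, in that 1 of 10 of its mRNAs rose and 6 fell, among them mt-Nd5 (-1.13) and mt-Nd2 (-1.09). So did mRNAs of cytosolic ribosomal proteins, where 2 of 80 members rose and 65 fell (3 and 66 adjusted over the list alone), among them Rpl26 (-1.001) and Rpl21 (-0.99). Whether the nuclear fractions of control and cKO were equally free of RNA from outside the nucleus was not tested. Of genes for proliferation and DNA replication, 3 of 28 genes rose and 23 fell, among them Mki67 (-0.95) and Top2a (-0.55). Of the p53 targets, 17 of 30 members rose and 7 fell, with Perp higher by 0.97 and Trp53inp1 by 0.74. These lists had adjusted p = 0.0274, 0.0075, 0.0274 and 0.0371 with an estimated correlation, in the order given. Small nucleolar RNA genes rose in 42 of 59 cases and fell in 1 (45 and 1 adjusted over the list alone), among them Snora41 (1.49) and Snord15a (1.10). The call of this list was lost with an estimated correlation (adjusted p = 0.328), and these genes lie in introns of host genes.

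Other lists in Mettl14 cKO held changed members without a call that lasted. For nuclear and chromatin-bound long noncoding RNAs, 13 of 29 members rose and 8 fell (14 and 8 adjusted over the list alone), among them the paraspeckle RNA Neat1 (1.07) and Rn7sk (0.61) (adjusted p = 0.143 with an estimated correlation). Its call was also lost without Mettl14 control replicate 1 (adjusted p = 0.0567). 10 of 24 immediate-early genes rose and 4 fell (11 and 4 adjusted over the list alone), with Dusp1 higher by 0.93 and Ccn2 by 0.72 (adjusted p = 0.0909 with an estimated correlation). 10 of 20 ERK targets rose and 3 fell, with Epha2 higher by 0.42 and Il17rd by 0.56 (adjusted p = 0.134 with an estimated correlation). Camera did not call the remaining lists. 3 of 17 formative and primed pluripotency genes rose and 9 fell, Nodal being higher by 0.85 and Dnmt3b lower (-0.56). 12 of 64 replication-dependent histone genes rose and 26 fell (12 and 27 adjusted over the list alone), among them Hist2h2ac (-1.12). Camera called the histone list when any 1 of the 8 libraries was left out, in fits that also tested more genes. 10 of 20 Wnt targets rose and 4 fell. 13 of 37 imprinted genes rose and 11 fell (14 and 12 adjusted over the list alone). 12 of 26 genes of the ATF4 and unfolded protein response rose and 8 fell (14 and 8 adjusted over the list alone). 10 of 23 genes of glycolysis and hypoxia rose and 8 fell (11 and 8 adjusted over the list alone). 3 of 17 trophectoderm genes rose and 5 fell. 2 of 17 neuroectoderm genes rose and 5 fell. 1 of 15 mesoderm and primitive streak genes rose and 1 fell. 5 of 33 Hox genes rose and 3 fell (3 and 3 adjusted over the list alone). 0 of 21 genes of the 2-cell-like state rose and 3 fell (0 and 2 adjusted over the list alone). 1 of 24 germline genes rose and 6 fell. 6 of 31 interferon response genes rose and 3 fell. The medians of trophectoderm and neuroectoderm (-0.03 and -0.02) had the opposite sign to their camera direction and turned positive with upper-quartile scaling. Without Mettl14 control replicate 2 these were 0.027 and 0.072, and they were as low as -0.090 without Mettl14 control replicate 1 and -0.16 without Mettl14 cKO replicate 1. Those of the 2-cell-like and imprinted lists (0.02 and 0.01) turned negative with RLE scaling. Without Mettl14 control replicate 1 they were 0.12 and 0.11, and without Mettl14 cKO replicate 2 -0.058 and -0.045 (2-cell-like without Mettl14 control replicate 2, -0.13). These 4 signs are therefore uncertain. The fits with 1 library left out also tested more genes, which can itself shift a median. With the median of genes of like GC content subtracted, the medians of 3 lists turned positive: m6A writers (0.057), trophectoderm (0.042) and germline genes (0.060).

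All 31 lists were fixed in advance. Counts adjusted over the list alone equal those over all genes tested where no second pair is given. Camera with its preset correlation called 18 lists in Mettl14 cKO, and 12 of the calls held with an estimated correlation. Silent genes moved with the same samples: 1460 olfactory and vomeronasal receptor genes together had 114.8 ± 8.92 CPM in Mettl14 control and 182 ± 9.22 in Mettl14 cKO (SD, n = 2). The lowest eighth of tested genes by mean abundance had a median log2 fold change of 0.63.

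**Figure D2:**
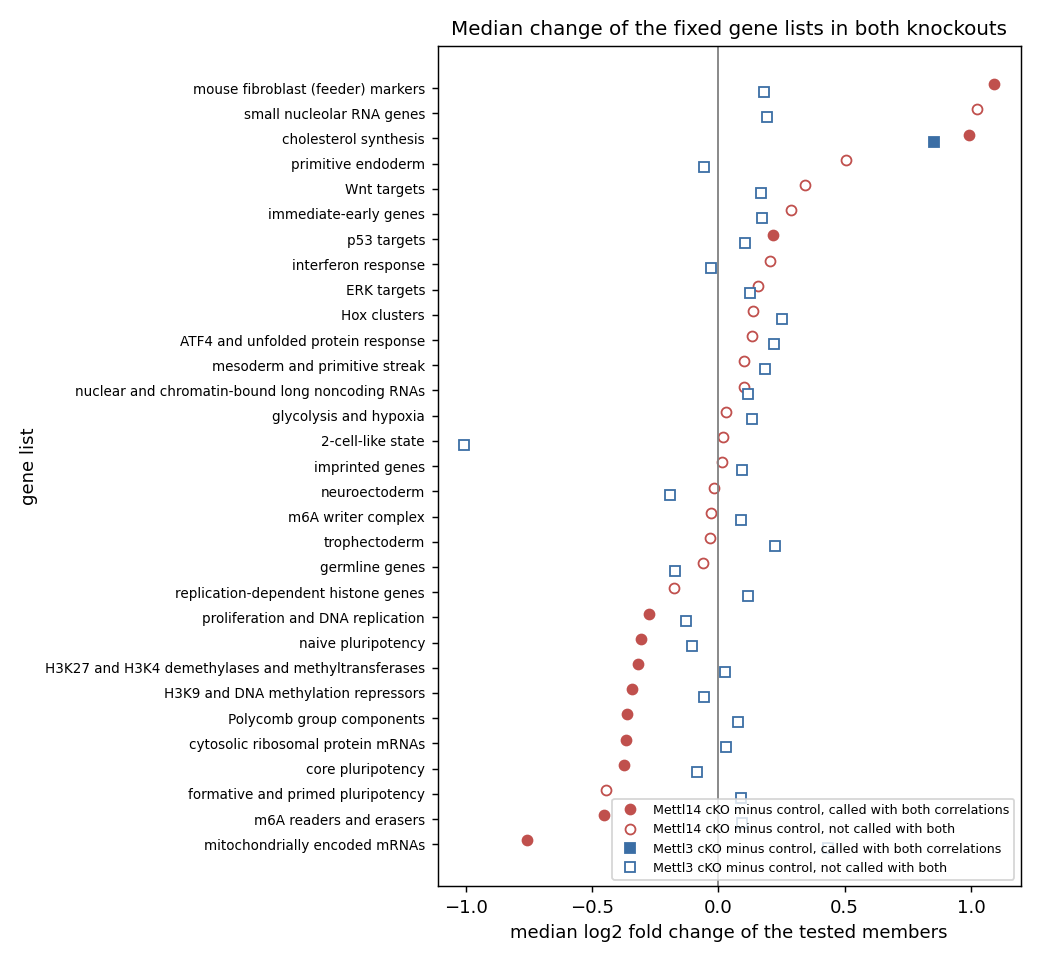
Median log2 fold change (x axis) of the tested members of each of the 31 lists (y axis) in Mettl14 cKO (circles) and Mettl3 cKO (squares). Filled symbols were called by camera with both the preset and an estimated correlation, 12 lists in Mettl14 cKO and 1, cholesterol synthesis, in Mettl3 cKO; with upper-quartile scaling the medians of 3 and 8 lists change sign.

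In Mettl3 cKO, genes of cholesterol synthesis rose, while Abca1 and Abcg1 fell. Nsdhl, a sterol dehydrogenase gene, rose by 1.14 ± 0.07 on the log2 scale and Cyp51 by 1.12 ± 0.04, while Abca1 fell by 1.30 ± 0.07, as did Abcg1 (-1.08 ± 0.28) (SE, n = 2 against 2). ABCA1 and ABCG1 carry cholesterol out of cells. The comparison asks which nuclear RNAs change when METTL3 is lost. Of 21782 tested genes, 4552 changed, 3292 up and 1260 down, of which 57 and 413 changed at least 2-fold. Genes with an average log2 CPM below 1 made up 50 of the rises and 431 of the falls. As the 2-fold counts were not split by abundance, their balance may rest on genes with few counts. The share of calls that rose was 72.3% with TMM scaling and 31.8% with upper-quartile scaling (1293 up and 2771 down), which shifts all fold changes by a median of -0.11. The direction of small changes therefore depends on the scaling.

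Among the highest rises by the fixed rule were Nsdhl and Cyp51, both of sterol synthesis, Fads2 (1.13 ± 0.07), a fatty acid desaturase, Syt7 (1.12), Bmyc (1.07) and Pigz (1.07). The largest falls were those of Abca1, the immediate-early gene Fosb (-1.18), Bhmt (-1.14), Cfap44 (-1.09), Nlrp4f (-1.08 ± 0.06), Abcg1 and the sodium channel gene Scn3a (-1.06 ± 0.10). The call of Syt7 was lost without Mettl3 cKO replicate 2 (adjusted p = 0.0816; range over all alternatives 0.000253 to 0.0816). Bhmt lost its call without Mettl3 cKO replicate 1 (log2 fold change -0.75, adjusted p = 0.27), without Mettl3 control replicate 1 (0.0625) or 2 (0.0756), without the low-count filter (0.0565) and in limma-voom (0.0542; range over all alternatives 0.00959 to 0.27).

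In cholesterol synthesis, 22 of 22 genes rose and 0 fell, with a median of 0.86 and a smallest change of 0.16. It was the 1 list of 31 whose call held with an estimated correlation (adjusted p = 0.000316), against 17 called with the preset one. Among core pluripotency genes 3 of 13 members rose and 5 fell (3 and 6 adjusted over the list alone), with Pou5f1 higher by 0.39, and camera did not call the list. 1 of 20 naive pluripotency genes rose and 8 fell (2 and 8 adjusted over the list alone), among them Nanog (-0.36) and Fgf4 (-0.33) (adjusted p = 0.111 with an estimated correlation). In the mitochondrial genome, 6 of 10 mRNAs rose and 0 fell (7 and 0 adjusted over the list alone), among them mt-Nd4 (0.55) and mt-Nd1 (0.49) (adjusted p = 0.0526 with an estimated correlation). 10 of 21 fibroblast markers rose and 2 fell (11 and 2 adjusted over the list alone) (median 0.18, adjusted p = 0.0526 with an estimated correlation), among them Fbln2 (0.34) and Col1a1 (0.28), from 2707 to 3294 CPM.

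**Figure D3:**
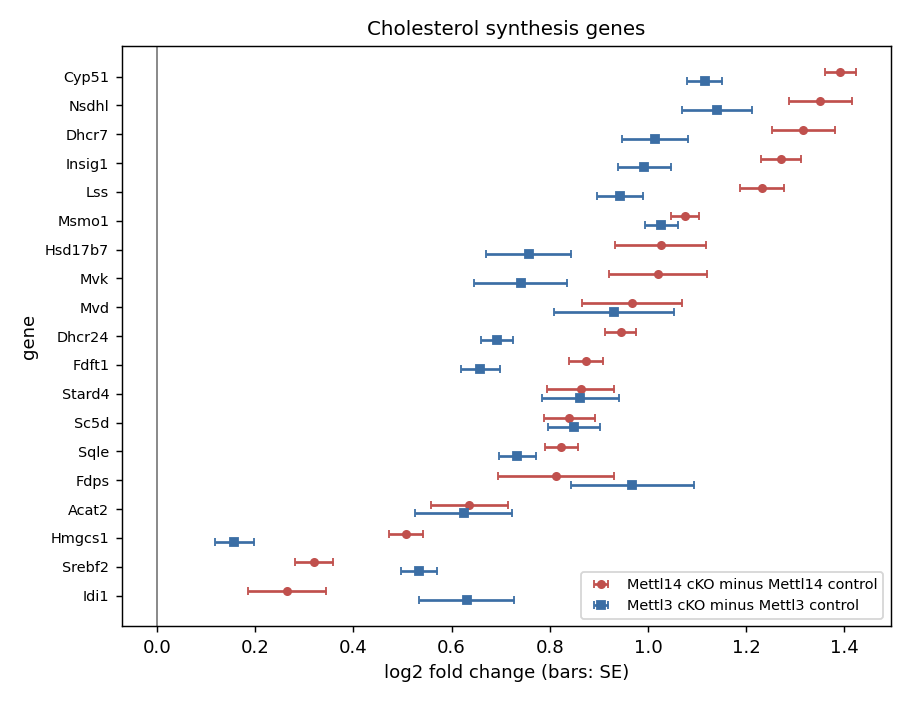
Log2 fold change (x axis, bars SE) of 19 of the 22 cholesterol synthesis genes (y axis) in Mettl14 cKO (circles) and Mettl3 cKO (squares), each against its own control. Every value lies above 0, and the medians over all 22 are 0.99 and 0.86.

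The other lists that camera called in Mettl3 cKO with the preset correlation lost the call with an estimated one. 13 of 26 genes of the ATF4 and unfolded protein response rose and 1 fell (19 and 2 adjusted over the list alone), among them the amino acid transporter genes Slc7a5 (0.57) and Slc3a2 (0.31) (adjusted p = 0.0526 with an estimated correlation). 3 of 28 genes of proliferation and DNA replication rose and 14 fell (4 and 16 adjusted over the list alone), among them Top2a (-0.28) and Mcm7 (-0.29). 12 of 23 genes of glycolysis and hypoxia rose and 0 fell (13 and 0 adjusted over the list alone), among them Slc2a1 (0.31) and Pkm (0.20). 14 of 30 p53 targets rose and 3 fell (16 and 3 adjusted over the list alone), among them Tnfrsf10b (0.30) and Cdkn1a (0.28) (adjusted p = 0.0809 with an estimated correlation for proliferation, glycolysis and p53 targets alike). 11 of 37 imprinted genes rose and 2 fell (11 and 3 adjusted over the list alone), among them Peg10 (0.42) and Kcnq1ot1 (0.28) (adjusted p = 0.111 with an estimated correlation). 7 of 14 m6A readers and erasers rose and 2 fell (7 and 4 adjusted over the list alone), among them the demethylase gene Alkbh5 (0.44) (adjusted p = 0.114 with an estimated correlation). 7 of 20 ERK targets rose and 3 fell, among them Spry4 (0.52), and 7 of 20 Wnt targets rose and 0 fell, among them Ccnd2 (0.35) and Axin2 (0.32), each list with an adjusted p = 0.114 with an estimated correlation. 11 of 24 immediate-early genes rose and 4 fell (13 and 4 adjusted over the list alone), the median being 0.17 and the mean -0.02 (adjusted p = 0.112 with an estimated correlation). 0 of 24 germline genes rose and 2 fell (0 and 1 adjusted over the list alone), among them Stk31 (-0.53) (adjusted p = 0.114 with an estimated correlation). Without Mettl3 control replicate 1 or Mettl3 cKO replicate 1 the germline call was lost (adjusted p = 0.0754 and 0.059). 10 of 29 long noncoding RNAs rose and 3 fell (11 and 4 adjusted over the list alone), among them Neat1 (0.44) and Malat1 (0.26) (adjusted p = 0.125 with an estimated correlation). 2 of 24 H3K9 and DNA methylation repressors rose and 7 fell (5 and 8 adjusted over the list alone), among them Dnmt1 (-0.22) and Uhrf1 (-0.21) (adjusted p = 0.185 with an estimated correlation). With 1 library left out that call lasted only without Mettl3 control replicate 2 (adjusted p = 0.0273 to 0.287 over the 8). 1 of 21 genes of the 2-cell-like state rose and 5 fell (1 and 6 adjusted over the list alone), with a median of -1.01 over members of low count. Eif1a rose by 0.32 and Pramef25 had 12 and 6 counts in control and 0 and 2 in cKO. The list's adjusted p was 0.185 with an estimated correlation and 0.0754 without Mettl3 control replicate 1, where its median was -0.53. Pramef25 was no longer called without Mettl3 control replicate 1 (adjusted p = 0.113) or Mettl3 cKO replicate 1 (0.132; range over all alternatives 0.00245 to 0.132).

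Camera called none of the following in Mettl3 cKO. 4 of 8 genes of the m6A writer complex rose and 1 fell. 9 of 32 Polycomb components rose and 4 fell (9 and 7 adjusted over the list alone), with Epop higher by 0.53. 5 of 18 H3K27 and H3K4 enzymes rose and 4 fell (6 and 4 adjusted over the list alone). 18 of 80 ribosomal protein mRNAs rose and 7 fell (21 and 7 adjusted over the list alone). 12 of 64 replication-dependent histone genes rose and 2 fell and 2 of 59 small nucleolar RNA genes rose and 1 fell (2 and 0 adjusted over the list alone). 4 of 17 formative and primed pluripotency genes rose and 4 fell (5 and 4 adjusted over the list alone). 4 of 16 primitive endoderm genes rose and 2 fell. 7 of 17 trophectoderm genes rose and 0 fell, among them Krt8 (0.22), and 3 of 15 mesoderm and primitive streak genes rose and 0 fell. 1 of 17 neuroectoderm genes rose and 2 fell. 2 of 33 Hox genes rose and 1 fell (0 and 0 adjusted over the list alone) and 3 of 31 interferon response genes rose and 0 fell (2 and 0 adjusted over the list alone). The medians of 8 lists changed sign with upper-quartile scaling: m6A writers, m6A readers and erasers, formative pluripotency, Polycomb, H3K27 and H3K4 enzymes, p53 targets, imprinted genes and ribosomal proteins. With the median of genes of like GC content subtracted, those of 7 lists turned negative: formative pluripotency, Polycomb, H3K27 and H3K4 enzymes, imprinted genes, ribosomal proteins, ERK targets (-0.024) and histone genes (-0.010). A further 9 medians shrank by more than 50% under this correction, among them immediate-early genes (0.048), glycolysis (0.042), p53 targets (0.019), trophectoderm (0.079) and fibroblast markers (0.079). With any 1 of the 8 libraries left out, camera called ribosomal proteins (adjusted p = 0.000115 to 0.0204). Trophectoderm was called without Mettl14 control 1, Mettl14 cKO 1 or Mettl3 cKO 2 (adjusted p = 0.0192 to 0.186 over the 8), and small nucleolar RNA genes without Mettl3 control 2 or Mettl3 cKO 1 (1.0e-13 to 0.516). Polycomb was called when any library of the Mettl14 line or Mettl3 cKO 2 was left out (adjusted p = 0.0214 to 0.0772 over the 8), and H3K27 and H3K4 enzymes without Mettl14 control 2, Mettl14 cKO 1 or 2, Mettl3 control 2 or Mettl3 cKO 2 (0.0147 to 0.0787). The fits with 1 library left out also tested more genes, so these calls need not rest on the library left out. Core pluripotency was called with RLE scaling (adjusted p = 0.0395). Silent receptor genes went down, from 414 ± 3.75 CPM in Mettl3 control to 238 ± 7.44 in Mettl3 cKO (SD, n = 2). The lowest eighth of tested genes had a median of -0.52.

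Genes that rose in both knockouts included all 22 members of the cholesterol list, and genes that fell in both included Nlrp4f and Rims1. Gpnmb rose by 2.13 in Mettl14 cKO and 0.56 in Mettl3 cKO. Nlrp4f fell by 1.01 in Mettl14 cKO and fell by 1.08 in Mettl3 cKO. Rims1, a presynaptic scaffold gene, fell by 1.54 and fell by 0.96. Besides these, high means of both changes belonged to Ccdc107 (2.63 and 0.63), Rnu1b6 (2.44 and 0.65), H2-M2 (1.78 and 1.06) and Mmp3 (1.89 and 0.94). The lowest belonged to Tchh (-1.98 and -0.38), Hmgn5 (-1.70 and -0.62), Nefm (-1.61 and -0.50) and Bhmt (-0.91 and -1.14). In the Mettl14 control libraries Mmp3 had 3 and 3 counts and H2-M2 4 and 2, so their folds rest on few reads. Leaving out 1 library ended the call of Rnu1b6 in Mettl3 cKO (without its replicate 2, adjusted p = 0.688). Its change there was 0.18 without that library and 1.06 without replicate 1. That of Hmgn5 in Mettl3 cKO was -0.37 without Mettl3 control replicate 1, and that of Bhmt -0.75 without Mettl3 cKO replicate 1. The call of Nefm ended in Mettl3 cKO (without its replicate 1, adjusted p = 0.126, or without Mettl3 control replicate 2, 0.103). Leaving out 1 library also ended those of H2-M2 in Mettl14 cKO (without Mettl14 control replicate 2, adjusted p = 0.149) and Mmp3 in Mettl14 cKO (without its replicate 2, 0.0723). Limma-voom also ended those of Rnu1b6 (0.0664) and H2-M2 (0.0505), and leaving out the low-count filter that of Nefm (0.0705). Over all alternatives the adjusted p ranged from 8.0e-06 to 0.688 for Rnu1b6, 0.00114 to 0.126 for Nefm, 0.00862 to 0.149 for H2-M2 and 0.00403 to 0.0723 for Mmp3.

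Of the genes called in both knockouts, 1841 of 2983 changed in the same direction. 1307 rose in both, against 593 for independent lists of that size (two-sided Fisher's exact test, p = 2.4e-229). 534 fell in both, against 282 (two-sided Fisher's exact test, p = 7.4e-60). 997 fell in Mettl14 cKO and rose in Mettl3 cKO, against 738, and 145 did the reverse, against 227. The split depends on the scaling. With upper-quartile scaling, 611 rose in both, against 262, and 1248 fell in both, against 550.2. There 323 fell in Mettl14 cKO and rose in Mettl3 cKO, and 399 did the reverse. All these expectations take every tested gene as equally likely to be called. Yet 4129 of 4880 falls in Mettl14 cKO and 2993 of 3292 rises in Mettl3 cKO were among genes with an average log2 CPM of at least 3. The expectations are therefore too low, so 997 against 738 need not be an excess, and the p-values partly reflect shared abundance. Genes are not independent replicates, and the knockouts were set against different control libraries. Across all tested genes the fold changes of the knockouts correlated at r = -0.16 (rho = -0.031). Across genes called in both this was r = 0.052 (rho = 0.30). Across the 10099 genes with an average log2 CPM of at least 3, a limit chosen after seeing the data, it was r = 0.26 (rho = 0.29). Only 23 genes passed the threshold in both in the same direction with at least 2-fold changes.

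The changes in Mettl14 cKO and in Mettl3 cKO differed from each other for core pluripotency genes, Polycomb and other histone-modifying enzymes, and mitochondrial mRNAs. Pou5f1 fell in Mettl14 cKO and rose in Mettl3 cKO, a difference of -1.61 ± 0.05 (SE), and Sox2 differed by -1.97 ± 0.09. Kdm6b differed by -2.19, Epop by -1.53 and mt-Nd1 by -1.62, the change in Mettl14 cKO being the lower in each case. The series title sets METTL14 apart from m6A. This contrast, the change in Mettl14 cKO minus that in Mettl3 cKO, tests each gene only for an unequal change. These libraries do not measure m6A, so the contrast cannot show an action of METTL14 apart from m6A. It called 7238 of 21782 genes, 2777 with a higher and 4461 with a lower change in Mettl14 cKO. With upper-quartile scaling, which shifts the contrast by a median of 0.16, the split was 4287 and 2788. Line and knocked-out gene changed together, so the difference between the knockouts and that between the lines cannot be separated. Nor was it tested whether the nuclear fractions were equally pure, on which the mitochondrial values may depend.

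By the fixed rule the highest differences were those of Rtl1 (3.02 ± 0.21), Lrrc7 (2.14), Mamdc2 (2.11), Dnah3 (2.05), Ccdc107 (2.00 ± 0.09) and the metalloprotease gene Adamts15 (1.99). The lowest were 5S ribosomal RNA genes, the ribosomal RNA-derived Mir6236 and Lars2 (-4.54 ± 0.08). The 5S genes had at most 4 counts in any library of the Mettl3 line, so their folds are uncertain. Of the lists, 7 differed with both the preset and an estimated correlation. Medians were lower in Mettl14 cKO for mitochondrial mRNAs (-1.16), core pluripotency (-0.46), H3K27 and H3K4 enzymes (-0.45), m6A readers and erasers (-0.44), ribosomal proteins (-0.38) and Polycomb components (-0.36), and higher for fibroblast markers (0.74). Their adjusted p with an estimated correlation were 0.0109, 0.0109, 0.00772, 0.00772, 0.00772, 0.0228 and 0.00772. The other lists that camera called with the preset correlation lost the call with an estimated one, among them naive pluripotency (median -0.13, adjusted p = 0.116 with an estimated correlation) and cholesterol synthesis (median 0.23, adjusted p = 0.0683). Formative pluripotency was not called. The mitochondrial median was -0.62 without Mettl3 control replicate 1 and -0.77 without Mettl3 cKO replicate 1. With upper-quartile scaling the medians of 4 lists turned positive in this contrast: naive pluripotency (0.028), the ATF4 response (0.059), glycolysis (0.059) and imprinted genes (0.091).

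More genes differed between the control groups than between either knockout and its control. Fibroblast markers were far higher in Mettl3 control, where Col1a2 had 1790 ± 66.6 CPM against 184 ± 0.353 in Mettl14 control and Col1a1 2707 ± 51.4 against 269.9 ± 5.74 (SD, n = 2). Pou5f1 was higher in Mettl14 control by 2.81 ± 0.03, Sox2 by 1.27 ± 0.06 and Zscan4d, a marker of the 2-cell-like state named after its value was seen, by 4.37 ± 0.32. Of 21782 genes, 14759 were called, 7329 higher and 7430 lower in Mettl14 control (5642 and 9450 with upper-quartile scaling, which shifts this contrast by a median of -0.22). This comparison gives the background on which the knockouts stand, and line and any batch cannot be separated in it.

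The lowest values in Mettl14 control relative to Mettl3 control were log2 differences of -4.02 for Mmp3, -3.73 for Ccdc107, -3.64 for Rtl1, -3.61 for Adra1d, -3.59 for H2-M2 and -3.56 for Cspg4. The highest were 5S ribosomal RNA genes, of which n-R5s194 had 4269 and 4837 counts in the Mettl14 control libraries and 0 and 1 in the Mettl3 control libraries, and Mir6236 (1723 and 2228 against 3 and 16). Usp17lc, of a near-identical family and likewise named after its value was seen, had 110 and 130 against 9 and 6 counts. Camera called 18 lists, and 16 of the calls held with an estimated correlation. Fibroblast markers had a median of -2.17, immediate-early genes -1.25 and primitive endoderm -0.86, lower in Mettl14 control. Higher there were histone genes (1.44), mitochondrial mRNAs (1.30), core (1.12) and naive pluripotency (1.07), ribosomal proteins (1.08) and cholesterol synthesis (0.62). With upper-quartile scaling the medians of 5 lists turned negative: formative pluripotency (-0.14), trophectoderm (-0.22), germline genes (-0.18), ERK targets (-0.21) and long noncoding RNAs (-0.031). The 2-cell-like list, with a median of 3.29, lost its call (adjusted p = 0.0965 with an estimated correlation).

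**Figure D4:**
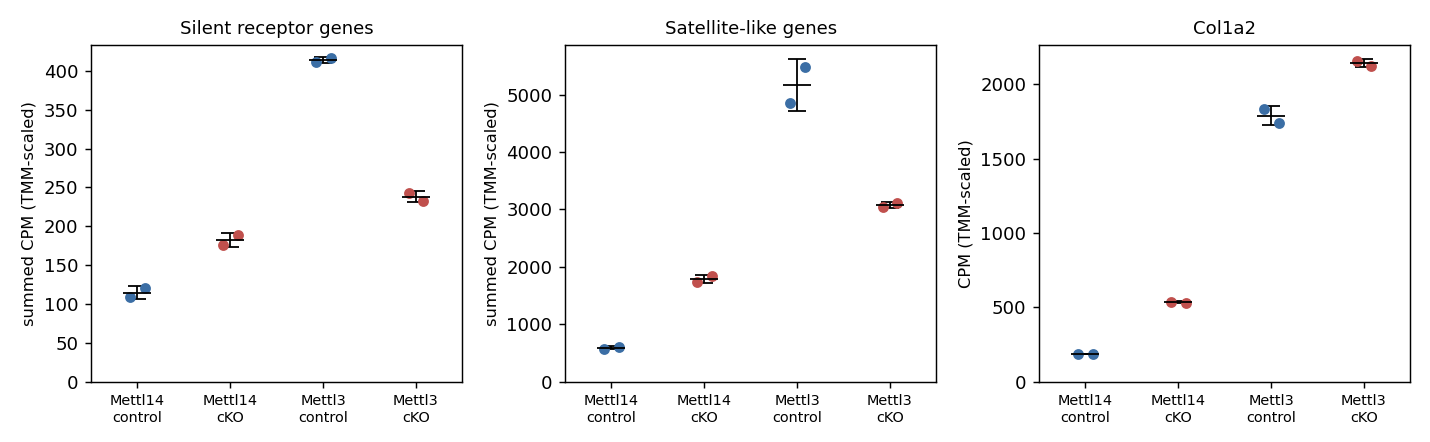
Summed CPM of silent receptor genes, summed CPM of genes that resemble the major satellite repeat, and CPM of Col1a2 (y axes) in each library (points) with the group mean and SD (black bars, n = 2). In the Mettl14 line the silent genes rise from 114.8 to 182 CPM and in the Mettl3 line they fall from 414 to 238, while Col1a2 is higher in both knockouts than in their controls.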

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

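The tests of the fibroblast share and of dilution by other cells were chosen after the result was seen, and the tests of GC content before. What singles out the results here is that the change in Mettl14 cKO and the change in Mettl3 cKO differed by the test of the difference itself. Of the 111 genes named, 88 differed, 42 with a higher and 46 with a lower change in Mettl14 cKO, and 23 of them moved in opposite directions with both changes called. 5 were not compared, as a line had at most 3 counts in each library. Most were named for large or clear changes in these data, some in this contrast, so a high share was built in. Of all 21782 tested genes, 7238 (33.2%) differed. These counts hold for TMM scaling, and upper-quartile scaling shifts the difference by a median of 0.157. Values are the log2 change in Mettl14 cKO minus that in Mettl3 cKO.

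7 lists differed, by their medians: mitochondrially encoded mRNAs (-1.16), core pluripotency (-0.46), H3K27 and H3K4 enzymes (-0.45), m6A readers and erasers (-0.44), ribosomal protein mRNAs (-0.38), Polycomb components (-0.36) and fibroblast markers (0.74). The mitochondrial median was -0.62 without Mettl3 control replicate 1 and -0.77 without Mettl3 cKO replicate 1.

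Among genes with a higher change in Mettl14 cKO, the highest differences were those of Pramef25 (3.17), Rtl1 (3.02), Lrrc7 (2.14), Mamdc2 (2.11), Dnah3 (2.05), Ccdc107 (2.00), Adamts15 (1.99), Snord23 (1.81) and Rnu1b6 (1.79). The next in size were Gpnmb (1.57), Abca1 (1.55), Cfap44 (1.53), Snora41 (1.35), Cspg4 (1.35), Fosb (1.30), Col1a2 (1.28), Adra1d (1.25) and Fbln2 (1.22). Below these came Snord15a (1.03), Mettl3 (0.97), Col4a1 (0.90), Perp (0.88), Nodal (0.72), Neat1 (0.63), Dusp1 (0.61), Trp53inp1 (0.56) and Sparc (0.53). Smaller differences belonged to Ccn2 (0.47), Tnfrsf10b (0.37), Ccnd2 (0.33), Rn7sk (0.31), Slc2a1 (0.30), Epha2 (0.29), Tdgf1 (0.29), Cyp51 (0.28) and Mcm7 (0.22). The smallest were Krt8 (0.21), Cdkn1a (0.21), Il17rd (0.20), Malat1 (0.19), Uhrf1 (0.17) and Dnmt1 (0.13). Pramef25 had 0 and 2 counts in the Mettl3 cKO libraries, so its value depends on how the fit treats counts near 0.

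Among genes with a lower change in Mettl14 cKO, the differences were most negative for Mir6236 (-5.40), Lars2 (-4.54), n-R5s193 (-4.12), Cited2 (-2.84), Zfp296 (-2.36), Bmyc (-2.25), Kdm6b (-2.19), Chchd10 (-2.09), Sox2 (-1.97) and mt-Nd1 (-1.62). Less negative values were those of Pou5f1 (-1.61), Tchh (-1.60), mt-Nd2 (-1.55), Epop (-1.53), mt-Nd4 (-1.52), Klf4 (-1.50), Prrc2a (-1.50), mt-Nd5 (-1.45), Hist2h2ac (-1.32) and Nefm (-1.11). Then followed Rpl21 (-1.08), Hmgn5 (-1.08), Alkbh5 (-1.08), Syt7 (-1.06), Mki67 (-1.06), Kdm1a (-1.04), Rpl26 (-1.02), Ythdc1 (-1.005), Mettl14 (-1.001) and Zc3h13 (-0.99). Next were Ezh2 (-0.99), Axin2 (-0.88), Cbx3 (-0.86), Mphosph8 (-0.85), Kdm5b (-0.83), Slc7a5 (-0.77), L1td1 (-0.76), Pkm (-0.66), Tet2 (-0.61) and Kcnq1ot1 (-0.51). The closest to 0 were Eif1a (-0.50), Peg10 (-0.42), Dnmt3b (-0.36), Top2a (-0.27), Spry4 (-0.18) and Slc3a2 (-0.17). In the Mettl3 line, n-R5s193 had 0 and 4 counts in control and 1 and 1 in cKO, and its call was lost without Mettl14 control replicate 2 (adjusted p = 0.058), Mettl14 cKO replicate 2 (0.0545), Mettl3 control replicate 1 (0.123) or Mettl3 cKO replicate 1 (0.164) or 2 (0.165). It was also lost with upper-quartile scaling (0.0538) and with no low-count filter (0.0731), and its value was -8.07 without Mettl3 control replicate 2.

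Fibroblast markers rose and core and naive pluripotency genes fell in Mettl14 cKO. A larger share of fibroblast RNA like that in the Mettl3 line would raise the markers alike: Col1a1, the most abundant, gained 2.78% of its difference between the lines, but the next in abundance, Col1a2, Col5a1, Fbln2 and Lox, gained 21.9, 19.7, 31.3 and 34.5%, and the median of 16 markers was 26.8% (range 2.78 to 45.0). Dilution by RNA of cells that lack the pluripotency transcripts would lower all 33 members alike. Their log2 fold changes had an SD of 0.51 where the median SE was 0.042, and 4 rose while 25 fell. RNA of cells that express some of these genes would spread the values too, so this spread cannot exclude dilution. Against GC content, the medians were 1.05 for the markers (before, 1.09) and -0.28 for the pluripotency genes (before, -0.34, SD 0.51) once the median of genes of like GC was subtracted. A larger share of fibroblast RNA stays open, as do, untested, cells with another expression profile, a difference in culture or batch, and loss of METTL14 acting on these genes.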

How the results depend on the processing

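The contrasts, lists, rule for named genes and alternatives were fixed before the data were examined, except the limit to genes with an average log2 CPM of at least 3, which was chosen after the result was seen. Total counts of called genes stayed within 1.5 times their value under RLE and upper-quartile scaling, under both low-count filters, in limma-voom and in the separate fit, which could not be made for the difference between knockouts. The split into up and down moved more. In Mettl3 cKO, 3292 up and 1260 down became 1293 and 2771 with upper-quartile scaling and 5814 and 559 with no filter, and in Mettl14 cKO 3921 and 4880 became 4420 and 4325 with upper-quartile scaling. DESeq2 called 2166 genes in Mettl3 cKO, 4714 for the difference and 991 in both knockouts in the same direction; the cause was not tested. An adjusted p under 0.01 left 2930 in Mettl3 cKO. Requiring a 2-fold change, a stricter limit by construction, left 1438 genes in Mettl14 cKO, 470 in Mettl3 cKO, 1690 for the difference, 6905 between controls and 23 in both. With fewer genes tested, those of average log2 CPM of at least 3, 8532 differed between controls.

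The correlation of fold changes between the knockouts, -0.161 over all tested genes, was -0.076 with no filter, -0.042 with at least 1 CPM in 2 libraries, 0.057 in the separate fits and 0.261 over genes with an average log2 CPM of at least 3, so its sign depends on which genes enter. Leaving out 1 library at a time gave -0.238 to -0.126, the lowest without Mettl14 control replicate 1, 7292 to 8985 genes in Mettl14 cKO, 3968 to 5329 in Mettl3 cKO, 6416 to 6927 for the difference, 13320 to 15541 between controls and 1574 to 1775 in both.

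With the replicate number as a block, 8783 genes were called in Mettl14 cKO, 4563 in Mettl3 cKO, 7172 for the difference, 14702 between controls and 1872 in both, with a correlation of -0.162, and no call of a gene chosen by the rule or of a list changed. The differences between replicates 1 and 2 correlated at -0.032 between control and cKO of the Mettl14 line and 0.072 in the Mettl3 line, and at 0.109 between the controls; with 2 numbers per group this does not show that they pair the samples.

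Of the results of genes chosen by the rule, many of them not named in the text, 0 lost the call under RLE scaling, 6 under upper-quartile scaling, 3 in DESeq2, 4 in limma-voom and 5 with no filter, and none of them changed sign. Results to which DESeq2 gave no adjusted p were left out of its count. There 195 stayed the same, against 213 under RLE scaling. Of the list calls, 32 over the 4 contrasts were lost with an estimated correlation, and fry, which asks another question, called 27 more in the same direction. For formative pluripotency between controls, camera pointed down without a call and fry up, with a median of 0.0787 (adjusted p = 0.00467); the tests differ in construction, and the median was 0.031 without Mettl3 control replicate 2 and 0.31 without Mettl14 control replicate 2. Depth limits calls among genes with few counts, as the recovery on simulated data shows.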

Other observations

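The tests of even background with genes chosen by the other line, of the satellite-like genes, of fibroblast RNA in the cholesterol genes and of the knockout changes against the difference between controls were chosen after the result was seen, and the tests of even background in all tested genes, library size and GC content before. Structural RNA classes are given by their share of counts in the 2 libraries of each group, without a test. Small nucleolar RNA took 0.264 and 0.289% in Mettl14 control and 0.651 and 0.626% in Mettl14 cKO, and 0.291 and 0.364% and 0.343 and 0.349% in the control and cKO of the Mettl3 line. Small Cajal body RNA, which guides the modification of spliceosomal RNA, took 0.0237 and 0.0241% and 0.0523 and 0.0515% in the Mettl14 line. Genes classed as microRNA went the other way there, from 0.801 and 0.823% in control to 0.189 and 0.189% in cKO. So did genes classed as ribosomal RNA, from 0.0368 and 0.0422% to 0.0093 and 0.0095%. The classes follow the annotation, so ribosomal RNA-derived genes such as Mir6236 are not in that share. In the Mettl3 line microRNA genes took 0.0525 and 0.0568% in control and 0.077 and 0.0652% in cKO. Genes classed as ribosomal RNA took 0.0335 and 0.0275% and 0.0413 and 0.0428% in that line. There the named 5S genes had at most 4 counts per library, so this share rests on other genes than in Mettl14 control. The mitochondrial genome took 2.99 and 3.00% in Mettl14 control, 1.43 and 1.43% in Mettl14 cKO, 1.06 and 1.12% in Mettl3 control and 1.26 and 1.33% in Mettl3 cKO. The purity of the nuclear fractions was not tested, so these shares need not reflect changes within the nucleus.

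Across 10099 genes with an average log2 CPM of at least 3, the change in Mettl14 cKO correlated at r = 0.67 with the difference Mettl3 control minus Mettl14 control (covariance 0.271). Simulated without effects, these were r = 0.52 and covariance 0.00397, the mean of 20 simulations, above 0 since both use the Mettl14 control libraries. The change in Mettl3 cKO correlated at r = -0.17 with Mettl14 control minus Mettl3 control (covariance -0.0279; simulated, 0.48 and 0.00347). The simulated r comes from noise in the shared control alone, so it is no baseline for the observed r, while the covariances can be compared. Of 7453 genes called both in Mettl14 cKO and between the controls, 6525 (87.5%) moved towards Mettl3 control. Of 3804 called both in Mettl3 cKO and between the controls, 1939 (51.0%) moved towards Mettl14 control. These counts share control libraries as well. Genes are not independent replicates.

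The least abundant eighth of tested genes rose in Mettl14 cKO and fell in Mettl3 cKO, as the silent receptor genes did. Reads spread evenly over the genome would move both by a like CPM per exonic kilobase, but the ratio of the changes was 2.80 in Mettl14 cKO (2.35 to 3.46 over pairs of libraries) and 2.04 in Mettl3 cKO (2.01 to 2.07), where the limit set in advance was 2. But 1640 of the 2576 genes had their highest mean in Mettl3 control, which helps them past the count filter and inflates their loss. With genes filtered and ranked on the libraries of the other line alone, the ratio was 2.54 in Mettl14 cKO (2.13 to 3.15) and 1.08 in Mettl3 cKO (0.998 to 1.16), which argues against even background as the whole cause in Mettl14 cKO and is consistent with it in Mettl3 cKO. Thinned to equal totals, the medians were 0.62 and -0.49 (before, 0.63 and -0.52), which argues against library size; background that is uneven along the genome, a difference in RNA or library preparation between the groups, and more or less transcription of weak genes stay open.

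A hypothesis was that 13 predicted genes that resemble the major satellite, the repeat next to mouse centromeres (42.3 to 71.8% of 15-mers), gain and lose reads from the same source as the silent receptor genes. Their summed CPM were 589 ± 25.8 in Mettl14 control, 1794 ± 71.6 in Mettl14 cKO, 5166 ± 451 in Mettl3 control and 3078 ± 60.1 in Mettl3 cKO (SD, n = 2). In Mettl14 cKO their log2 ratio to receptor counts moved by 0.94 (0.89 to 0.99 over pairs), beyond the limit of 0.5, and 9 of 13 were called up. Under a shared source, reads that either set has of its own would move this ratio too. The test therefore cannot exclude a shared source in Mettl14 cKO. In Mettl3 cKO the ratio moved by 0.0548 (-0.077 to 0.19), which is consistent with a shared source there, and 7 were called down. Copies of this repeat cannot be told from each other by short reads, and a change of satellite transcription is only 1 of several possible sources of the rise in Mettl14 cKO.

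The rise of cholesterol synthesis genes in both knockouts was set against GC content and against a larger share of fibroblast RNA, which can raise no gene more than the fibroblast markers themselves. In Mettl3 cKO the median of the cholesterol genes lay 0.69 above that of 16 abundant markers on the log2 scale, and 21 of 22 exceeded the highest marker (0.49), which argues against such RNA for these genes. In Mettl14 cKO, where the markers rose, the medians differed by -0.104, so it stays open there. With the median of genes of like GC subtracted, the medians were 1.02 in Mettl14 cKO and 0.75 in Mettl3 cKO (before, 0.99 and 0.86), which argues against GC content. That loss of METTL3 raises these transcripts is a hypothesis; a difference in medium, serum or cell density between control and cKO cultures, which sterol genes follow, stays open and was not tested.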
